A study of Homo sapiens with 16 samples.

How the data were processed

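ATAC-seq, which marks open chromatin by the insertion of Tn5 transposase, was done on IMR90 lung fibroblasts carrying an inducible B-RAF fusion, in 16 libraries: 4 replicates each of Raf-inactive and Raf-active cells, in normoxia and in hypoxia at 0.5% oxygen. Per the submitters' processing notes, FastQC, cutadapt, Bowtie2, SAMtools, Picard, deepTools, bedtools and MACS2 were used with the human assembly hg38, with no versions, settings or blacklist stated. The authors deposited 1 narrowPeak list per library, and replicates were not pooled. Per the submitters' processing notes and the column order, each line holds a score, which is a multiple of the -log10 q rounded down. It also holds the fold enrichment at the summit as a ratio over the local background computed for the authors, and the -log10 p and -log10 q of the authors' peak caller. The score, the ratio and the -log10 values depend on a library's depth and were used only to rank, filter or describe peaks within a list. Signal tracks and reads were not used here.

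Lines with the same interval were merged into 1 peak, and chromosomes 1 to 22 and X were kept. Peaks that share a start and end but have several summits count once. The files state no read totals. The background pileup was therefore recovered from the listed fold and -log10 p, which fit a ratio of pileup plus 1 to background plus 1 with a Poisson p. The pileup at each summit was chosen to match the listed p. It did so for 100% of peaks, those with the smallest p left out, which is no check of the recovery. The background of a library was the value at which its commonest folds were whole multiples of a constant. It explained 100% of them in the other groups but 76.7%, 76.7%, 81.7% and 86.7% in the 4 Raf-inactive normoxia libraries, so it is less sure there, and the lowest of these set the target of matching. The background ranged from 3.01 to 8.34 between libraries, and is a measure of background coverage, not a read count. Lists matched in depth were made by binomial thinning of each recovered pileup to the lowest background, keeping a -log10 p of at least 5, while peak lengths stayed as called at full depth. A list holds only peaks past the caller's threshold, so absence means not called at that depth.

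Each library gave 4 values: distinct peaks, Mb covered, the percent of peaks within 1 kb of either end of a protein-coding gene, and the percent in gene-poor 1-Mb bins. The gene-poor bins were the fifth of bins with the fewest protein-coding genes, 608 of 3043, with at most 1 gene each. Differences between groups were tested with exact permutation tests (two-sided, 4 against 4), whose smallest p is 0.0286, and Benjamini-Hochberg adjusted over 20 tests. Merged regions came from the union of the 16 lists, 355405 in all, of which 299037 had peaks of at least 2 libraries. A region was gained or lost when 4 of 4 libraries of one group and 0 of 4 of the other had an overlapping peak. Similarity was the Jaccard index of covered base pairs.

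For genes, peaks were counted in the gene body plus 10 kb on each side, scaled to the same total over loci, and taken as log2 of the scaled number plus 1. Loci with a mean of at least 3 peaks were fitted in limma 3.58.1 (R 4.3.3) with all 16 libraries and 4 group means, 15175 in all, and called at an adjusted p below 0.05. The same was done for 2437 bins of 1 Mb with a mean of at least 10 peaks. The interaction was the Raf change in hypoxia minus that in normoxia. For single values its exact permutation exchanged oxygen labels within each Raf state, which tests for no oxygen effect rather than for no interaction alone. Of 23 gene lists 22 had enough tested members, and defensins were left out. Lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation. Camera compares a list with the other loci, so its direction can differ in sign from a median or mean; this was so for none of the called lists. It was so for HIF targets in every comparison but Raf in hypoxia, for cell cycle genes in all but the interaction and hypoxia in Raf-inactive cells, and for arrest and senescence genes with Raf in normoxia and hypoxia in Raf-inactive cells. It was also so for glycolysis genes and keratin-associated proteins in both Raf comparisons, HOX genes with Raf in normoxia, and interferon response genes and clustered protocadherins with Raf in hypoxia. It held further for ZNF genes in hypoxia with Raf inactive, and for endothelial markers and histone proteases in hypoxia with Raf active. Neighbouring loci overlap and share peaks, as in the histone, HOX, protocadherin and keratin-associated clusters, so members of a list are not independent.

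The groups, comparisons, gene lists and alternatives were fixed before the data were examined, except for those named here and in the closing section as added. The genes named were the 6 largest rises and 6 largest falls per comparison among called loci whose groups did not overlap, up to 4 members of each called list in its direction, and 12 fixed genes for Raf and 12 for hypoxia. For the interaction they were the 4 largest of each sign. Regions named were the 3 gained and 3 lost with the highest mean rank of the authors' -log10 p within each list, of which some are given. Other fixed genes past the interaction test are named as well.

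The annotation gave gene positions, symbols and biotypes, with 19974 protein-coding genes on the chromosomes used, but no strand, transcripts or sequence. The planned promoter share was therefore replaced by the share at gene ends, and the nearest transcription start by the nearest gene within 100 kb. Motifs and GC content were not analysed here. The fit was tested on simulated data of 15175 loci. Of 100 loci planted with a log2 change of 0.5, 67 were called, and of 100 with a change of 1, 99 were. There were 10 false calls among the loci without a planted change, and 0 calls in a comparison with none planted. Changes were planted only at loci above a minimum peak number, as many up as down, with independent noise. Few loci changed there, so the simulation does not test the scaling when many loci change, as in these data. For regions the changes were planted so as to meet the calling rule itself. Recovery of 200 of 200 was therefore fixed beforehand and is no check of the rule. A further 825 regions met the rule without a planted change. Presence there was drawn at each region's share over all libraries, including regions that differ with Raf. The 825 are therefore no measure of false calls.

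Alternatives covered the peak threshold (-log10 q or fold of at least 5), equal list length, scaling, pseudocount, locus width, base pairs in place of peak number, autosomes alone, bin size, 500-bp tiles, the rule for gained regions, the replicate number as a block and each library left out in turn. Depth matching and the share at gene ends were added after seeing the data. Values were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and drawn with matplotlib 3.10.9.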

Results

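The accessibility of chromatin to Tn5 transposase was measured by ATAC-seq in IMR90 cells, a line of human lung fibroblasts, carrying a retroviral B-RAF fused to the estrogen receptor, which 4-hydroxytamoxifen switches on. Sustained Raf signalling of this kind drives fibroblasts into oncogene-induced senescence, and the question was how hypoxia changes chromatin accessibility in that state. The 16 libraries fell into 4 groups of 4 replicates: Raf-inactive and Raf-active cells, each in normoxia or in hypoxia at 0.5% oxygen. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Each library had its own peak list, with between 169287 and 206757 distinct peaks on the autosomes and chromosome X. The background coverage behind the lists, which stands in for depth here, differed between groups. The background pileup averaged 3.23 in Raf-inactive and 6.75 in Raf-active normoxia, and 4.78 and 7.31 in hypoxia (n = 4 each). Coordinates are those of hg38, counted from 1.

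The 4 groups formed separate blocks, and Raf status parted the libraries more than oxygen did. The mean Jaccard index of covered base pairs was 0.737 within and 0.412 between the groups for Raf in normoxia, and 0.775 within and 0.455 between for Raf in hypoxia. For hypoxia it was 0.739 within and 0.654 between in Raf-inactive cells, and 0.774 within and 0.641 between in Raf-active cells. Each difference gave an exact permutation p of 0.0286 (two-sided, 4 against 4), the smallest this design allows.

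**Figure D1:**
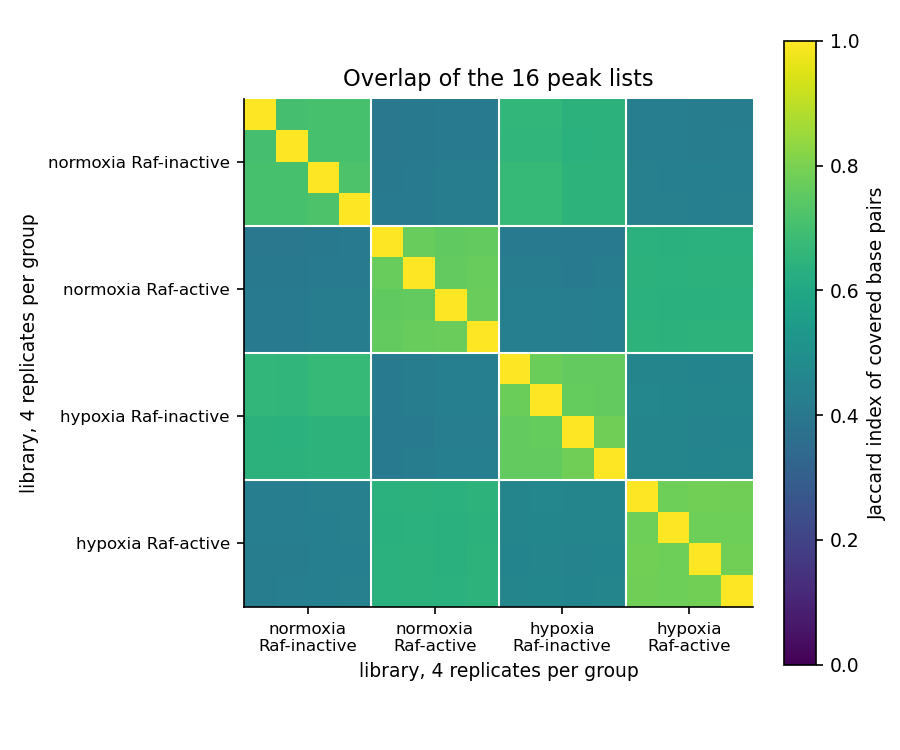
Jaccard index of covered base pairs for every pair of the 16 peak lists, on a scale from 0 to 1, with white lines between the groups of 4 replicates. The blocks within groups are brightest, the blocks across oxygen at equal Raf status come next (means of 0.654 and 0.641), and the blocks across Raf status are darkest (means of 0.412 in normoxia and 0.455 in hypoxia).

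With Raf active in normoxia, peaks appeared at loci that had almost none in Raf-inactive cells and vanished from others. TRIM63, a ubiquitin ligase best known from muscle, went from 0 peaks to 7.44 ± 1.09 (SD, n = 4) scaled peaks per locus, and TERT, the catalytic subunit of telomerase, from 0.803 ± 1.02 to 10.1 ± 2.16. The log2 change was 3.07 ± 0.15 (SE) for TRIM63, followed by MATK at 2.93, OBP2B at 2.82, TERT at 2.78 ± 0.29, KRTAP12-4 at 2.73 and CHST15 at 2.59. THEMIS, a T-cell signalling gene on chromosome 6 from 127696628 to 127918595, lost nearly all its peaks, from 14.0 ± 1.55 to 0.221 ± 0.442, and fell by 3.68 ± 0.17 on the log2 scale. The next largest falls were HHLA2 at -3.48, the ADP receptor gene P2RY12 at -3.38, LMO3 at -3.38, the metalloproteinase gene ADAMTS19 at -3.21 and HMGCLL1 at -3.16. Since the log2 values carry a pseudocount of 1 peak, they understate the change of loci near 0.

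Among the 12 loci fixed in advance, those of senescence and secretory genes moved in both directions in normoxia. IL1B, an inflammatory cytokine gene, rose by 1.19 ± 0.13 (log2, SE; adjusted p 1.03e-07), the cell cycle inhibitor locus CDKN2A by 0.92 ± 0.11 (adjusted p 5.61e-07), CXCL8 by 0.49, IL1A by 0.42 and HMGA2 by 0.34. LMNB1, which encodes lamin B1 of the nuclear lamina, fell by 0.92 ± 0.11 (adjusted p 3.84e-07), and DUSP6, a phosphatase acting on ERK, fell by 0.86 ± 0.14. IL6 at 0.25, CDKN1A at 0.23, MMP1 at 0.14, SPRY4 at 0.10 and MMP3 at -0.00 did not pass the test. The direction turned among peaks of at least 5-fold enrichment for IL1A (-0.28) and HMGA2 (-0.80), and the CDKN2A call ended there (0.02). It turned with base pairs in place of peak number for DUSP6 (0.34), with the nearest gene for DUSP6 (0.66) and CXCL8 (-0.04), and with loci widened to 50 kb for CXCL8 (-0.01).

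**Figure D2:**
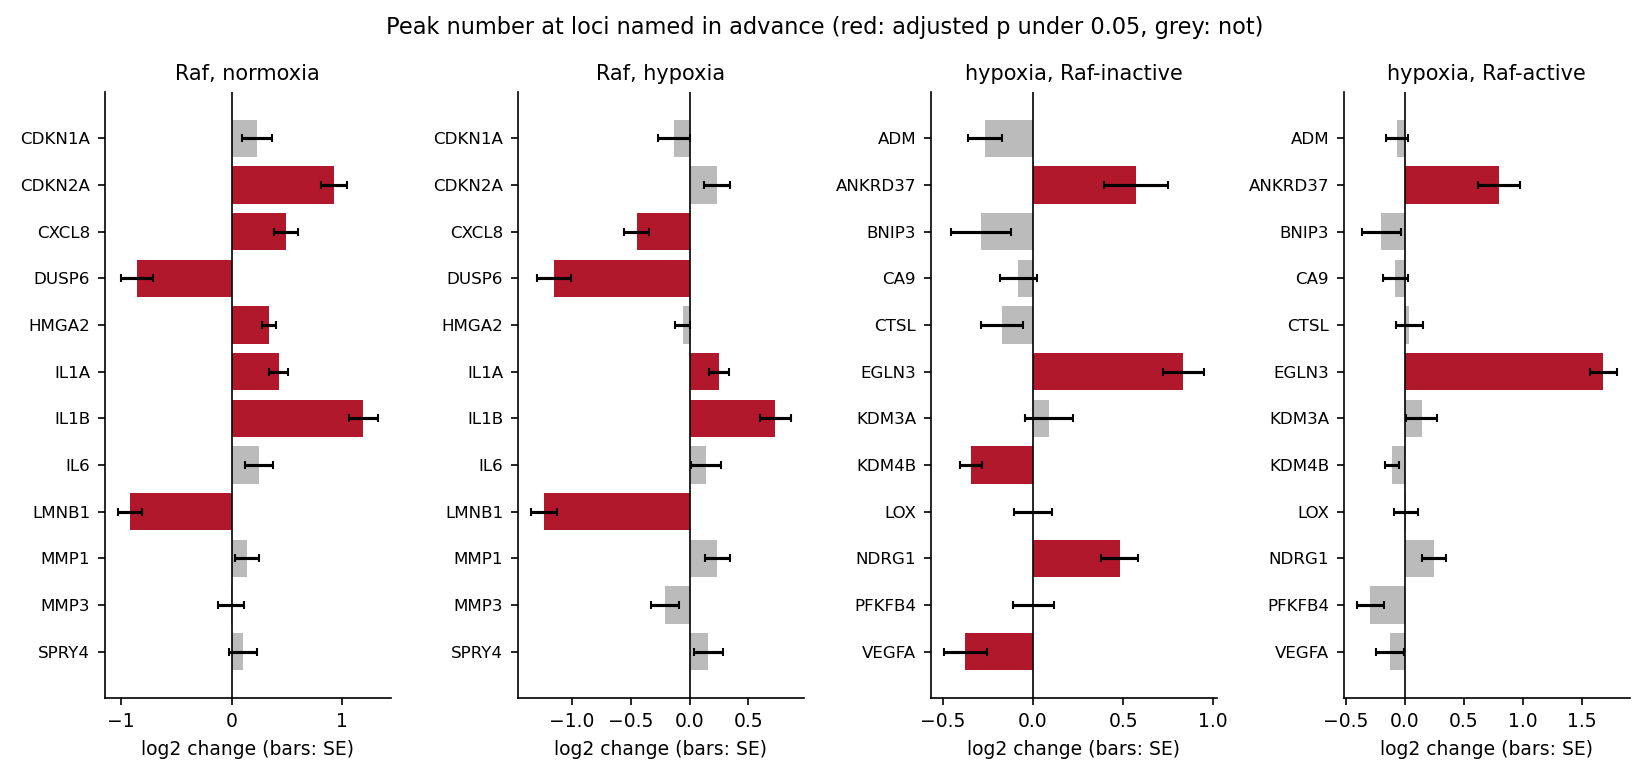
Log2 change in scaled peak number at the 12 loci fixed in advance for Raf and the 12 fixed for hypoxia, with standard errors from the fit to 16 libraries, in red where the adjusted p passed and in grey where it did not. IL1B was higher and LMNB1 lower with Raf active at both oxygen levels, and EGLN3 and ANKRD37 were higher in hypoxia at both Raf states. DUSP6 is lower here in peak number but higher in base pairs covered (0.34 in both oxygen conditions).

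Over all 15175 loci tested, 9563 changed in normoxia, of which 5684 rose and 3879 fell (limma with Benjamini-Hochberg adjustment). No fixed gene list as a whole passed the camera test at the preset correlation. Of 65 histone genes 9 rose and 31 fell (adjusted p 0.0584, and adjusted p = 0.454 with an estimated correlation), of 297 ZNF genes 128 rose and 47 fell (adjusted p 0.247, and adjusted p = 0.0318 with an estimated correlation), and of 22 clustered protocadherins 12 rose and 0 fell (adjusted p 0.247). Of 50 genes of the senescence-associated secretory phenotype 20 rose and 8 fell, of 47 RAF-MAPK response genes 23 rose and 6 fell, of 40 arrest and senescence genes 13 rose and 14 fell, and of 48 cell cycle genes 16 rose and 13 fell. Fibroblast matrix genes split into 9 that rose and 13 that fell of 45. Chromatin architecture genes split into 15 and 8 of 41, histone lysine methyltransferases into 16 and 7 of 34, demethylases into 9 and 6 of 21, and histone proteases and cathepsins into 7 and 3 of 18. HIF targets split into 17 and 17 of 62, glycolysis genes into 5 and 6 of 23, interferon response genes into 7 and 9 of 31, HOX genes into 10 and 9 of 29, olfactory receptors into 6 and 10 of 24 and keratin-associated proteins into 4 and 6 of 13. Markers of other cell types did so too: 8 of 19 epithelial markers rose and 1 fell, with 10 and 4 of 18 for endothelial, 11 and 1 of 17 for blood and 6 and 7 of 15 for neuronal markers. Adjusted over the list alone, the counts changed only for epithelial markers (6 up, 0 down), cell cycle genes (15 and 13) and HIF targets (17 and 16). The split depended on the scaling: unscaled, 77.6% of the called loci were higher in place of 59.4%, and the median change over all loci was 0.33 in place of 0.10. Many of these families lie in clusters whose loci share peaks, so their members are not independent.

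By region, 42240 merged regions were gained and 31830 lost with Raf active in normoxia, meaning a peak in 4 of 4 libraries of one group and in 0 of 4 of the other. Ranked by the authors' -log10 p within each list, the highest gained regions were an intergenic one on chromosome 2 from 218377803 to 218378626, 3647 bp from SLC11A1, an iron transporter gene, and one inside CPNE5 on chromosome 6 from 36755157 to 36756259. Both were also called without active Raf in hypoxia, in 2 of 4 Raf-inactive libraries near SLC11A1 and in 4 of 4 inside CPNE5. The highest lost regions were on chromosome 5 from 117803356 to 117804023, inside TRPM3 on chromosome 9 from 70953779 to 70954708, and inside JAZF1 on chromosome 7 from 28106233 to 28107044. At matched depth, a setting chosen after seeing the data, 31626 regions were gained and 32470 lost. The count of regions gained was 24800 among peaks of at least 5-fold enrichment and 65563 by a rule of at least 3 of 4 against at most 1 of 4.

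**Figure D3:**
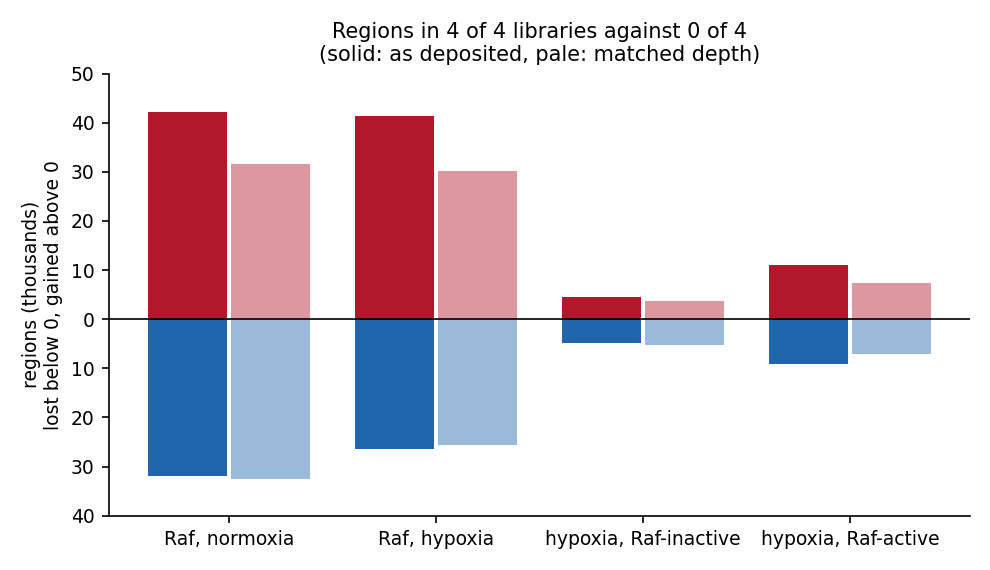
Merged regions gained (above 0) and lost (below 0) in each of the 4 comparisons, scaled as the axis states, by the rule of 4 of 4 libraries against 0 of 4, for the lists as deposited (solid) and at matched depth (pale). Raf in normoxia gave 42240 gained and 31830 lost regions as deposited, and hypoxia in Raf-inactive cells 4474 and 4756.

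Fewer peaks were called in gene-poor parts of the genome with Raf active. The 608 gene-poor bins of 1 Mb held 5.50% ± 0.02 of the peaks in Raf-inactive normoxia and 3.47% ± 0.15 in Raf-active normoxia (SD, n = 4), and 5.93% ± 0.05 and 3.94% ± 0.01 in hypoxia. The number of peaks there fell by 2792 in normoxia and fell by 2305 in hypoxia, and of the lost regions 9.47% and 10.6% lay in these bins, against 5.03% of all regions. Hypoxia went the other way, adding 0.433 percentage points in Raf-inactive and 0.462 in Raf-active cells. All 4 differences in share gave an exact permutation p of 0.0286 (adjusted 0.044 over 20 tests), with every library of one group below every library of the other. The Raf difference was -2.02 percentage points in normoxia and -1.99 in hypoxia, and the difference between these was 0.029 (exact permutation p = 0.902). That permutation exchanged oxygen labels within each Raf state, so its p tests for no oxygen effect and cannot show that the Raf differences are equal.

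**Figure D4:**
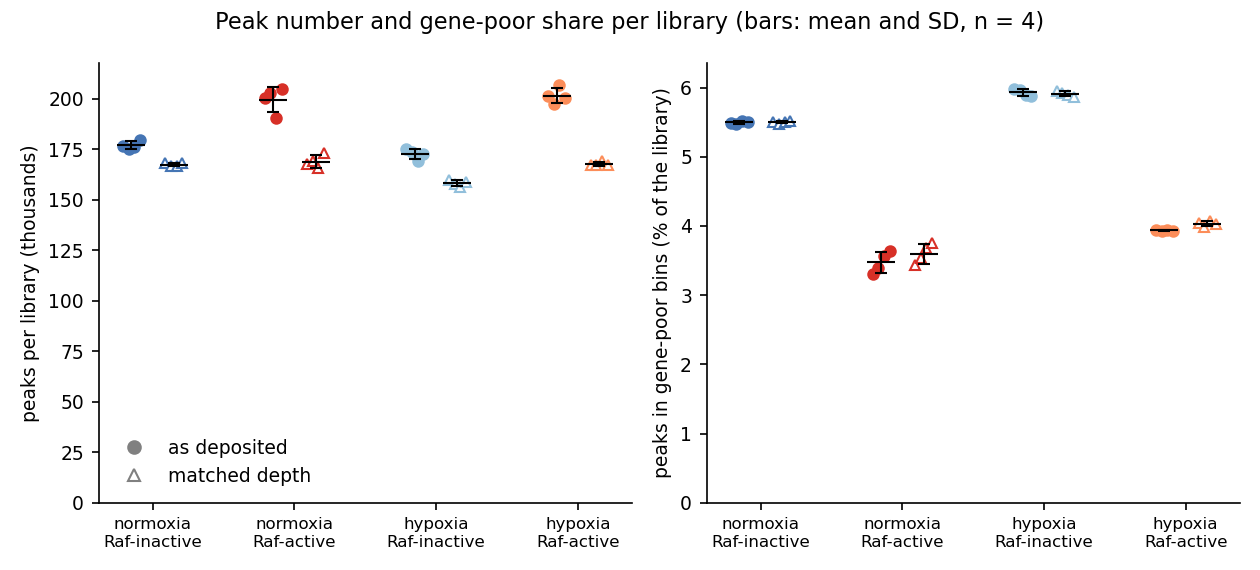
Peaks per library, scaled as the axis states (left), and percent of each library's peaks in gene-poor bins (right) for the 4 groups, as deposited (filled circles) and at matched depth (open triangles), with the mean and SD of 4 libraries. The gene-poor share was lower in every Raf-active library in both versions, whereas the surplus of peaks with Raf active in normoxia shrank from 22605 to 1470 at matched depth.

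The same redistribution appeared along the chromosomes. Of 2437 bins of 1 Mb, 850 rose and 1296 fell with Raf active in normoxia, and 915 rose and 1218 fell in hypoxia (limma). Across bins, which are not independent replicates, the change with Raf followed gene density with a Spearman rho of 0.528 in normoxia and 0.500 in hypoxia. The change with hypoxia ran against gene density, with a rho of -0.353 in Raf-inactive and -0.389 in Raf-active cells. Without scaling, 51.1% and 58.2% of the called bins were higher with Raf active, in place of 39.6% and 42.9%.

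Raf-active libraries listed more peaks, 199560 ± 6372 against 176955 ± 1900 in normoxia and 201539 ± 3829 against 172688 ± 2439 in hypoxia (SD, n = 4, exact permutation p = 0.0286 for each). They covered 90.2 against 79.4 Mb and 98.8 against 80.6 Mb (exact permutation p = 0.0286 each). The surplus of genome covered by peaks was 10.8 Mb in normoxia, 4.69 at matched depth and 1.97 among peaks of at least 5-fold enrichment, and 18.2 Mb in hypoxia, 12.4 and 7.45. Matching dropped peaks but kept the lengths called at full depth, so these covered lengths were matched only in part. At matched depth the surplus of peaks was 1470 in normoxia (exact permutation p = 0.457) and 9422 in hypoxia (exact permutation p = 0.0286). Among peaks of at least 5-fold enrichment the difference in number was -1614 in normoxia and -282 in hypoxia. The share of peaks within 1 kb of either end of a protein-coding gene differed by 0.221 percentage points with Raf in normoxia (exact permutation p = 0.0571) and by -0.510 in hypoxia (exact permutation p = 0.0286). The normoxia value of this share of peaks at gene ends was -0.0804 at a -log10 q of at least 5, 0.583 at matched depth, 0.597 at equal list length and 1.20 within 2 kb. The hypoxia value turned to 0.174 among peaks of at least 5-fold enrichment, to 0.117 at equal list length and to 0.078 within 2 kb, and was -0.0767 at matched depth.

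With Raf active in hypoxia, TRIM63 again led the rises, at 2.997 ± 0.146 (log2, SE), followed by the gastric mucin gene MUC6 at 2.84, the aquaporin gene AQP12B at 2.82, IDI2 at 2.82, the sulfotransferase gene SULT1A2 at 2.71 and ZDHHC11 at 2.66. CNTN1, a neural cell adhesion gene, fell by 3.27 ± 0.19, from 8.69 ± 1.02 (SD, n = 4) scaled peaks to 0. The next largest falls were HMGCLL1 at -3.22, NECAB1 at -2.97, NOL4 at -2.87, SPARCL1 at -2.76 and ADAMTS19 at -2.74. LMNB1 fell by 1.24 ± 0.11 (adjusted p 6.08e-09), DUSP6 fell by 1.15 and CXCL8 fell by 0.45, while IL1B rose by 0.73 ± 0.13 and IL1A by 0.25. CDKN2A at 0.23, MMP1 at 0.24, SPRY4 at 0.16, IL6 at 0.14, HMGA2 at -0.06, CDKN1A at -0.13 and MMP3 at -0.21 did not pass. IL1A turned to -0.52 and CDKN2A to -0.32 among peaks of at least 5-fold enrichment. In base pairs DUSP6 turned to 0.34 and HMGA2 to 0.08, by the nearest gene DUSP6 turned to 0.35, at matched depth the IL1A call ended (0.10), as it did without Raf-active hypoxia replicate 3 (0.19), and unscaled the CXCL8 call ended (-0.24) and HMGA2 was at 0.20. Without Raf-inactive or Raf-active hypoxia replicate 3, MMP1 (0.32 each) and CDKN2A (0.29 each) passed, as did MMP3 without Raf-inactive hypoxia replicate 1 (-0.35).

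Here 9091 loci changed, 5145 up and 3946 down, and 2 lists were called. Of 45 fibroblast matrix genes 5 rose and 23 fell, also adjusted over the list alone (camera adjusted p 0.0199, and adjusted p = 0.248 with an estimated correlation). Among those that fell were FBN2, a fibrillin gene, at -1.11, the collagen genes COL11A1 at -1.81 and COL5A2 at -0.55, and ACTA2, smooth muscle actin, at -0.72. Of 65 histone genes 6 rose and 25 fell, or 6 and 24 adjusted over the list alone (camera adjusted p 0.0199, and adjusted p = 0.250 with an estimated correlation), with H1-2 at -0.65, H2BC4 at -0.63, H2AC15 at -0.57 and H4C6 at -0.54. H2AC15 turned to 0.014 among peaks of at least 5-fold enrichment, and the H2BC4 call ended with loci widened to 50 kb (-0.17). The calls of fibroblast matrix and histone genes ended at matched depth (adjusted p 0.121 for both), at equal list length (0.108 for both), unscaled (0.101 and 0.0777) and among peaks of at least 5-fold enrichment (0.541 and 0.431), and that of fibroblast matrix at a -log10 q of at least 5 (0.111). No epithelial marker fell and 9 of 19 rose, or 8 adjusted over the list alone (adjusted p 0.0807). Of 17 blood markers 8 rose and 2 fell (adjusted p 0.530), of 18 endothelial markers 5 and 4 (adjusted p 0.661) and of 15 neuronal markers 6 and 6 (adjusted p 0.551). Of 50 secretory genes 9 rose and 11 fell, or 8 and 10 adjusted over the list alone (camera adjusted p 0.551). Unscaled, 78.4% of called loci were higher in place of 56.6%, with a median change of 0.29 in place of 0.06.

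In hypoxia 41393 regions were gained and 26388 lost with Raf active. The 3 highest gained lay inside GNPAT on chromosome 1 from 231274078 to 231274865, on the same chromosome from 11728020 to 11728572, 2163 bp from DRAXIN, and inside EHMT1, a histone methyltransferase gene, on chromosome 9 from 137688584 to 137689213. The 3 highest lost lay on chromosome 4 from 128573715 to 128574191, 235509 bp from JADE1, on chromosome 7 from 55307970 to 55308766, 56571 bp from LANCL2, and inside the interferon-inducible gene IFI16 on chromosome 1 from 159039709 to 159041133. Among peaks of at least 5-fold enrichment the count of regions gained was 23101.

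Much of the Raf response was shared between the oxygen conditions. Of the regions gained in normoxia 20865 were also gained in hypoxia, where 5847 would be shared by independent lists, and of those lost 16175 were also lost, against 2809. The values for independent lists count all 299037 regions. Of these 78755 had a peak in all 16 libraries and could change in neither condition, so the excess is overstated. Only 39 regions gained in normoxia were lost in hypoxia and 48 lost in normoxia were gained. Of the loci, 3856 rose in both, against 1927 for independent lists, and 2808 fell in both, against 1009. Of the regions lost in normoxia, 76.3% had no peak in any Raf-active hypoxia library and 9.10% had one in 4 of 4, among them the regions in TRPM3 and on chromosome 5 named above.

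Hypoxia alone, in Raf-inactive cells, moved fewer loci: 970 rose and 1121 fell, 2091 in all, against 3687 in base pairs covered and 1417 in a fit to these 8 libraries alone. CXCR4, a chemokine receptor gene, rose by 1.98 ± 0.24 (log2, SE), from 1.08 ± 0.87 to 6.74 ± 1.62 scaled peaks (SD, n = 4), followed by COL6A5, a collagen gene, at 1.52, the endothelial receptor gene KDR at 1.45, the tissue factor gene F3 at 1.37, TMEM233 at 1.29 and SCGB2A2 at 1.29. All but COL6A5 had their lowest mean in Raf-inactive normoxia, the group of lowest background. With Raf in normoxia the log2 change was 1.55 for CXCR4, 1.07 for KDR, 1.44 for F3 and 1.59 for TMEM233. In that comparison SCGB2A2 went from 0.532 to 4.27 scaled peaks and COL6A5 from 2.16 to 1.57. DFFB, which encodes an apoptotic nuclease, fell by 1.37 ± 0.13, followed by AKR1C2 at -1.36, NLRC3 at -1.33, CSE1L at -1.28, EPPK1 at -1.21 and ZNF562 at -1.17. EGLN3, a HIF target that encodes a prolyl hydroxylase acting on HIF, rose by 0.83 ± 0.11 (adjusted p 0.000101), the HIF target ANKRD37 by 0.57 and NDRG1 by 0.48. The demethylase gene KDM4B fell by 0.34 and VEGFA fell by 0.38. KDM3A at 0.09, LOX at 0.00, PFKFB4 at 0.00, CA9 at -0.08, CTSL at -0.17, ADM at -0.27 and BNIP3 at -0.29 did not pass.

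HIF targets as a list were not called, with 7 up and 3 down of 62, or 12 and 5 adjusted over the list alone (adjusted p 0.442), nor were 23 glycolysis genes, with 1 up and 0 down (adjusted p 0.232), nor 21 demethylases, with 0 up and 5 down (adjusted p 0.0945). HOX genes rose as a list, with 8 of 29 up and 0 down, or 12 adjusted over the list alone (camera adjusted p 0.00082, and adjusted p = 0.245 with an estimated correlation). HOXC4 rose by 1.01, and HOXC5 and HOXC6, whose loci share the same peaks and lie within that of HOXC4, by 1.18. These rises are therefore not separate. HOXC11 rose by 0.75. The histone gene list was called (adjusted p 0.0428, and adjusted p = 0.296 with an estimated correlation) although H1-10 alone rose, by 0.43, of 65 genes, and 0 passed adjusted over the list alone. H3C6 was at 0.30 and H2AC25 and H2BC26, which share peaks, at 0.32. For HOX genes the adjusted p was 0.0732 at matched depth and 0.220 among peaks of at least 5-fold enrichment. The call of histone genes ended with the replicate number as a block (0.0519), at a -log10 q of at least 5 (0.224) and among peaks of at least 5-fold enrichment (0.255). It also ended without any of 4 single libraries, with 0.109 and 0.106 without Raf-inactive normoxia replicates 1 and 4 and 0.116 and 0.0503 without Raf-inactive hypoxia replicates 1 and 2. Markers of other cell types were not called as lists: 4 of 18 endothelial markers rose and 0 fell, or 5 adjusted over the list alone (adjusted p 0.0945), 1 of 17 blood markers rose and 0 fell, or 3 adjusted over the list alone (adjusted p 0.0945), 2 of 15 neuronal markers rose and 0 fell (adjusted p 0.434), and 0 of 19 epithelial markers rose and 2 fell (adjusted p 0.626).

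The NDRG1 rise turned to -0.88 among peaks of at least 5-fold enrichment, and the VEGFA fall turned to 0.18 in base pairs and ended at matched depth (-0.33) and without any single Raf-inactive library other than normoxia replicate 3 and hypoxia replicate 4 (from -0.37 to -0.32). The H1-10 call ended without Raf-inactive hypoxia replicate 2 (0.38) or 3 (0.37). H3C6 passed without hypoxia replicate 3 (0.40), and H2AC25 and H2BC26 without normoxia replicate 2 or hypoxia replicate 3 (0.41 each). ADM passed without normoxia replicate 3 (-0.31) or hypoxia replicate 4 (-0.32), and BNIP3 without hypoxia replicate 1 (-0.52). In base pairs BNIP3 was at 0.26, and with loci widened to 50 kb ADM was at 0.20. The ANKRD37 call ended without Raf-inactive normoxia replicate 1 (0.35) or 2 (0.55) or Raf-inactive hypoxia replicate 3 (0.51) or 4 (0.52). By region, 4474 were gained and 4756 lost, the highest gained inside ZFAND5 on chromosome 9 from 72362703 to 72363044 and the highest lost on chromosome 2 from 238945772 to 238946097, 35238 bp from TWIST2. By a rule of at least 3 of 4 against at most 1 of 4 the number of regions gained was 14396 and of regions lost 16124. Of the gained regions 9.59% lay in gene-poor bins and of the lost 5.28%. Without scaling 28.2% of called loci were higher in place of 46.4%.

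Hypoxia lowered the number of peaks per library in Raf-inactive cells, by a difference of -4268 (exact permutation p = 0.0286), while in Raf-active cells the difference was 1979 (exact permutation p = 0.657). The covered length differed by 1.16 Mb (exact permutation p = 0.486) and 8.59 Mb (exact permutation p = 0.0286). At matched depth the difference in peaks per library with Raf active turned to -1262, and that in genome covered by peaks with Raf inactive to -0.162 Mb. Peak lengths were again those called at full depth. With Raf inactive the covered length stayed higher in hypoxia at a -log10 q of at least 5 (78.0 against 74.5 Mb). The same held among peaks of at least 5-fold enrichment (64.3 against 61.5 Mb) and at equal list length (79.7 against 77.4 Mb). The share of peaks at gene ends differed by 0.497 percentage points (exact permutation p = 0.0286) and by -0.234 (exact permutation p = 0.114). At matched depth the difference in peaks with Raf inactive was -9214, and it turned to 4605 at a -log10 q of at least 5 and to 1095 among peaks of at least 5-fold enrichment, where the difference in the share of peaks at gene ends was -0.000575, against 0.158 at a -log10 q of at least 5.

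In Raf-active cells hypoxia moved 2061 loci up and 2160 down, 4221 in all, against 6532 with loci widened to 50 kb. ICA1, an islet autoantigen gene, rose by 2.71 ± 0.13 (log2, SE), from 0 to 5.60 ± 0.79 scaled peaks (SD, n = 4), followed by SMYD1, a methyltransferase gene of muscle, at 2.62, FGF13 at 2.49, DCHS2 at 2.44, the tenascin gene TNR at 2.40 and SKOR2 at 2.12. RO60 fell by 1.60 ± 0.22, followed by NBN, which takes part in DNA break repair, at -1.59, the kinase gene PRKD3 at -1.50, GFPT1, an enzyme of hexosamine synthesis, at -1.47, POMK at -1.41 and COL19A1 at -1.33. EGLN3 rose by 1.68 ± 0.11 (adjusted p 1.61e-09) and ANKRD37 by 0.80 ± 0.18. NDRG1 at 0.25, KDM3A at 0.15, CTSL at 0.04, LOX at 0.01, ADM at -0.06, CA9 at -0.08, KDM4B at -0.10, VEGFA at -0.12, BNIP3 at -0.20 and PFKFB4 at -0.29 did not pass. PFKFB4 did pass without Raf-active normoxia replicate 1 (-0.37) or Raf-inactive hypoxia replicate 2 (-0.29), and NDRG1 without Raf-inactive hypoxia replicate 1 (0.25). NDRG1 was at -1.18 among peaks of at least 5-fold enrichment.

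No gene list was called there by the preset test, though calls arose among peaks of at least 5-fold enrichment, at matched depth and unscaled. Of 62 HIF targets 9 rose and 3 fell, or 9 and 2 adjusted over the list alone (adjusted p 0.496), of 50 secretory genes 3 rose and 10 fell (adjusted p 0.351), of 41 chromatin architecture genes 4 rose and 11 fell, or 4 and 12 adjusted over the list alone (adjusted p 0.206), and of 297 ZNF genes 24 rose and 60 fell, or 24 and 61 adjusted over the list alone (adjusted p 0.206, and adjusted p = 0.0212 with an estimated correlation). By region, 11042 were gained and 9154 lost. The highest gained were on chromosome 10 from 93968405 to 93969040, 24891 bp from PLCE1, and from 49577195 to 49578132, 30963 bp from CHAT, and the highest lost was on chromosome 17 from 50806840 to 50807412, 27172 bp from WFIKKN2. Among peaks of at least 5-fold enrichment the number of regions gained was 7206 and of regions lost 5848, and by a rule of at least 3 of 4 against at most 1 of 4 they were 24417 and 22200. Unscaled, 38.0% of the called loci were higher in place of 48.8%, and scaled to the whole list 34.8%.

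The Raf response differed between the oxygen conditions at 2962 loci, 1507 with a higher and 1455 with a lower Raf change in hypoxia (limma interaction), against 1278 and 1758 when scaled to the whole list. SMYD1 differed by 3.41 ± 0.39 (log2, SE), with a Raf change of -1.40 in normoxia and 2.01 in hypoxia, ICA1 by 2.24, SKOR2 by 2.00 and PHACTR3, a phosphatase regulator gene, by 1.95. NECAB1 differed by -2.03, CXCR4 by -1.97, NBN by -1.77 and PRKD3 by -1.66. Of the loci fixed in advance, CDKN2A differed by -0.69 ± 0.16 (adjusted p 0.00503), CXCL8 by -0.95, HMGA2 by -0.39 and EGLN3 by 0.85. No list was called, the lowest adjusted p being 0.0924 for chromatin architecture genes (1 up and 12 down of 41, or 2 and 14 adjusted over the list alone) and for clustered protocadherins (0 and 0 of 22). Of 50 secretory genes 1 had a higher and 10 a lower Raf change in hypoxia (camera adjusted p 0.102, and adjusted p = 0.370 with an estimated correlation). The share of peaks at gene ends differed by -0.730 percentage points (exact permutation p = 0.00163), by -0.354 at a -log10 q of at least 5 and by -0.0665 among peaks of at least 5-fold enrichment (exact permutation p = 0.631). In peaks per library the difference was 6246 (exact permutation p = 0.135), at matched depth 7952 (exact permutation p = 0.0282), and it turned to -2774 at a -log10 q of at least 5 (exact permutation p = 0.531). These permutations exchanged oxygen labels within each Raf state, so they test for no oxygen effect and decide nothing on the interaction. In base pairs covered 4911 loci differed in place of 2962, and among peaks of at least 5-fold enrichment the PRKD3 call ended (-0.27).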

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

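The tests on depth, weak peaks, dilution, mixed cells and other splits of the libraries below were all chosen only after the results were seen, as was the share of peaks at gene ends, while the interaction tests of loci and bins were planned. In 44 tests for a single sample far from the others, over several measures in each of the 4 groups, 0 samples stood apart. Each set the gap at an end of 4 values against their range, so 2 replicates apart from 2 go unseen. Raf-inactive normoxia had median summit pileups of 39, 39, 44 and 44, which gave 0. In Raf-inactive hypoxia the Jaccard index was 0.776 for replicates 1 and 2, 0.782 for 3 and 4, and 0.758 to 0.762 across. In the other groups the pairs across were not all lower.

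The Raf response differed between normoxia and hypoxia at 2962 loci and 1176 bins past the interaction test. The difference in the share of peaks at gene ends was -0.730 percentage points (exact permutation p = 0.00163, adjusted 0.0327). Among peaks of at least 5-fold enrichment this difference in the share of peaks at gene ends was -0.0665. The permutation exchanged oxygen labels within each Raf state, so its p tests for no oxygen effect. It decides nothing on an interaction. Of 86 named genes tested, 41 differed, 22 with a positive and 19 with a negative log2 interaction. The Raf change was higher in hypoxia for SMYD1 by 3.41, ICA1 by 2.24, SKOR2 by 2.00, PHACTR3 by 1.95, TNR by 1.86, DCHS2 by 1.83 and FGF13 by 1.50. Of the 6 loci named for a large fall with Raf in normoxia, 4 had a smaller one in hypoxia by this test, with HHLA2 at 1.72, THEMIS at 1.45, LMO3 at 1.19 and P2RY12 at 1.05, while ADAMTS19 at 0.47 and HMGCLL1 at -0.06 did not pass. Other positive values were 1.62 for AKR1C2, 1.23 for NLRC3, 1.21 for DFFB, 1.11 for MUC6, 1.05 for EPPK1, 1.00 for SULT1A2, 0.96 for ZDHHC11, 0.93 for IDI2, 0.85 for EGLN3, 0.59 for ZNF562 and 0.29 for COL5A2.

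Negative values, a lower Raf change in hypoxia, were -2.03 for NECAB1, -1.97 for CXCR4, -1.77 for NBN, -1.66 for PRKD3, -1.56 for F3, -1.53 for GFPT1, -1.53 for COL19A1, -1.49 for KDR and -1.34 for RO60. HOXC5 and HOXC6, which share peaks with each other and with HOXC4, were at -1.32, and HOXC4 was at -0.999. POMK was at -1.08, CHST15 at -1.04, TMEM233 at -0.97, CXCL8 at -0.95, CDKN2A at -0.69, H2AC15 at -0.49 and HMGA2 at -0.39. Genes were named for their largest change in a single comparison, which favours extreme values in 1 group and with it an interaction.

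Of 100 draws of the libraries for the interaction, the real one included, 2 gave at least 2962 loci and 2 gave at least 1176 bins. These draws exchange oxygen labels, so they test for no oxygen effect rather than for no interaction, and decide nothing on the interaction itself. The highest other draw gave 4197 loci and 1422 bins. It exchanged the oxygen labels of all 8 Raf-inactive libraries, so by construction it measured the sum of the oxygen effects in both Raf states. The oxygen effect common to both Raf states was then removed from each locus and bin. There 1 of 100 draws, the real one, gave as many as its 2916 loci or 1177 bins, and the highest other draw gave 1 and 1. This rank argues against chance in how these 16 libraries were grouped, within the limit of 100 draws. That says nothing of the spread between separate cultures. For the other comparisons 1 of 35 splits, the real one, gave as many loci, bins or regions. The 9563, 9091, 2091 and 4221 loci stood against a highest other split of 1, 0, 8 and 1 (Raf in normoxia, Raf in hypoxia, hypoxia with Raf inactive and with Raf active). In the same order 2146, 2133, 693 and 1562 bins stood against 0, 0, 6 and 0, and 74070, 67781, 9230 and 20196 regions against 210, 179, 429 and 389.

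The lower share of peaks in gene-poor bins with Raf active was weighed first. At matched depth the difference was -1.90 percentage points in normoxia and -1.88 in hypoxia, and among peaks of at least 5-fold enrichment it was -1.62 in both, with no overlap of libraries, which argues against depth or weak peaks as the whole cause. The number of gene-poor peaks itself fell by 2792 and fell by 2305, which argues against dilution by peaks elsewhere. A change in the chromatin of gene-poor regions in Raf-active cells may account for it, as a hypothesis found and tested on the same data. Copy number, mappability and GC bias were not tested. The median local background at peaks, over the background of the library, was 1.82 with Raf active against 1.47 in normoxia. In hypoxia it was 1.67 against 1.44. Since peaks are called over the local background, fewer peaks need not mean less accessible chromatin, and this was not tested either.

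The larger number of peaks with Raf active was weighed next. At matched depth the difference was 1470 in normoxia, where depth may account for nearly all of the 22605 extra peaks. It was 9422 in hypoxia, with no overlap of libraries, which argues against depth as the whole cause of the 28851 there. Among peaks of at least 5-fold enrichment the difference was -1614 in normoxia and -282 in hypoxia, so extra weak peaks at a lower signal over background stay open in both. The background that was matched may itself follow signal over background, whose median fold fell from 6.51 to 5.78 in normoxia and from 7.12 to 5.85 in hypoxia, so matching need not act through depth alone.

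Of the regions lost with Raf in normoxia, 9.10% had a peak in 4 of 4 Raf-active hypoxia libraries. At matched depth it was 6.42%, which argues against depth as the whole cause. Among regions also present in all Raf-inactive hypoxia libraries, the share was 25.0% among the strongest and 6.22% among the weakest of 10 equal classes, as cells without the Raf response mixed into these cultures could give. Incomplete loss within every cell predicts the same trend, and so does a response that hypoxia weakens. No test here parts them.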

How the results depend on the processing

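Depth matching and all values of the share at gene ends were chosen only after seeing the data, and the other alternatives were planned. A tested value counted as kept when its direction and side of the threshold held. Counts and percents counted as kept within a set fold. A rho, or a value per library or similarity with a library left out, counted as kept within a set spread. Paired sign flips were counted as kept whatever their p. Of the results that answer a comparison, 326 were kept under alternatives, 54 moved, 8 reversed, 7 passed a threshold newly and 6 no longer did. With single libraries left out, 614 were kept and 26 moved. For named genes and called lists, 1252 were kept, 57 moved, 18 reversed, 58 newly passed and 42 no longer passed. With single libraries left out 1932 of these were kept, 19 moved, 16 newly passed and 17 no longer did. Named loci under the minimum peak number in a stricter list were not tested there and are missing from these counts. Among peaks of at least 5-fold enrichment 25 named-gene results were kept, 7 moved, 7 reversed, 4 newly passed and 2 no longer did. With a pseudocount of 0.5, where no locus was lost, 120 were kept. The cause was not tested for any change below. Depth limits every count, since a site can go uncalled in a shallow library. Motifs, GC-poorest bins and the promoter share were not run, and peaks at equal list length give no value.

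Among peaks of at least 5-fold enrichment, the difference in peaks per library reversed to -1614 (Raf in normoxia), -282 (Raf in hypoxia) and 1095 (hypoxia, Raf inactive), and the covered length with Raf in normoxia was 1.97 Mb. The share of peaks at gene ends reversed to 0.174 with Raf in hypoxia and -0.000575 with hypoxia in Raf-inactive cells, and its interaction was -0.0665. The number of regions gained was 24800 and 23101 with Raf in normoxia and hypoxia, and 7206 with hypoxia in Raf-active cells, where that of regions lost was 5848. The rho of bins with gene density was 0.441, 0.453, -0.284, -0.259 and -0.0969 for Raf in normoxia, Raf in hypoxia, hypoxia with Raf inactive, with Raf active, and the interaction. Peak number reversed there for IL1A (-0.28 in normoxia, -0.52 in hypoxia), HMGA2 (-0.80 in normoxia), H2AC15 (0.014, Raf in hypoxia), CDKN2A (-0.32, Raf in hypoxia) and NDRG1 (-0.88 with Raf inactive, -1.18 with Raf active). The lists called were 0 with Raf in hypoxia, 0 and 2 with hypoxia in Raf-inactive and Raf-active cells, and 1 for the interaction.

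At a -log10 q of at least 5, the difference in peaks reversed to 4605 with hypoxia in Raf-inactive cells and was -2774 for the interaction. The share of peaks at gene ends was -0.0804 with Raf in normoxia and 0.158 with hypoxia in Raf-inactive cells. The rho was 0.508 with Raf in normoxia and -0.373 with hypoxia in Raf-inactive cells, and the lists called were 2 with Raf in normoxia, 1 in hypoxia and 1 for the interaction.

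Matched to the shallowest library, peaks differed by 1470 (Raf in normoxia), -1262 (hypoxia, Raf active) and 7952 (interaction). Covered Mb differed by 4.69 with Raf in normoxia, -0.162 with hypoxia in Raf-inactive cells and 7.66 for the interaction. Peak lengths there stayed as called at full depth. The share of peaks at gene ends differed by 0.583 and -0.0767 with Raf in normoxia and hypoxia. The rho was -0.321 and -0.365 with hypoxia in Raf-inactive and Raf-active cells. The lists called were 1 and 0 with Raf in normoxia and hypoxia, 1 and 1 with hypoxia in Raf-inactive and Raf-active cells, and 2 for the interaction.

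At equal list length the share of peaks at gene ends was 0.597 with Raf in normoxia, reversed to 0.117 with Raf in hypoxia and was -0.120 with hypoxia in Raf-active cells. The gene-poor interaction was -0.00296, rho for the interaction was -0.189, and the lists called were 1 and 0 with Raf in normoxia and hypoxia. Within 2 kb of a gene end the share was 1.20 with Raf in normoxia, reversed to 0.0785 with Raf in hypoxia and was -0.512 with hypoxia in Raf-active cells. By the rule of at least 3 of 4 against at most 1 of 4, the number of regions gained was 65563 with Raf in normoxia, 14396 with hypoxia in Raf-inactive and 24417 in Raf-active cells, and that of regions lost 16124 and 22200 with hypoxia.

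In base pairs covered, 3687 loci changed with hypoxia in Raf-inactive cells and 4911 in the interaction. The rho was -0.376, -0.369 and -0.183 there for hypoxia in Raf-inactive cells, in Raf-active cells and the interaction. In base pairs DUSP6 reversed to 0.34 with Raf in normoxia and 0.34 in hypoxia, HMGA2 to 0.085 with Raf in hypoxia, and VEGFA to 0.18 and BNIP3 to 0.26 with hypoxia in Raf-inactive cells. With loci widened to 50 kb, 6532 loci changed with hypoxia in Raf-active cells, CXCL8 reversed to -0.0077 with Raf in normoxia and ADM to 0.20. By the nearest gene CXCL8 reversed to -0.044 and DUSP6 to 0.66 with Raf in normoxia, and DUSP6 to 0.35 in hypoxia. With no filter on peak number rho was -0.413 with hypoxia in Raf-inactive cells and -0.112 for the interaction. Unscaled, HMGA2 reversed to 0.20 with Raf in hypoxia, and the lists called were 2 and 0 with Raf in normoxia and hypoxia and 1 with hypoxia in Raf-active cells. With an estimated correlation the lists called were 1 and 0 with Raf in normoxia and hypoxia, and 0 and 1 with hypoxia in Raf-inactive and Raf-active cells.

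Replicate numbers did not pair the samples: same-number correlations ran from -0.0850 to 0.0332. A fit to only the 8 libraries of a comparison gave 1417 loci with hypoxia in Raf-inactive cells. With the replicate block in the fit, 9489, 8999, 2009, 4125 and 2835 loci changed in the order of comparisons above, and 1 list, HOX genes, was called with hypoxia in Raf-inactive cells, as the call of histone genes ended (adjusted p 0.0519). Paired sign flips cannot give a p below 0.125. With single libraries left out, rho ran from -0.362 to -0.335 with hypoxia in Raf-inactive cells, from -0.422 to -0.345 in Raf-active cells and from -0.253 to -0.154 for the interaction. The lists called ran from 0 to 1 with Raf in normoxia, 1 to 2 with hypoxia in Raf-inactive cells, 0 to 1 in Raf-active cells and 0 to 1 for the interaction. It was 1 with Raf in normoxia without Raf-inactive normoxia replicate 1 or 4 or Raf-active normoxia replicate 3, and 1 with hypoxia in Raf-inactive cells without normoxia replicate 1 or 4 or hypoxia replicate 1 or 2. It was 1 with hypoxia in Raf-active cells without normoxia replicate 4 or hypoxia replicate 1. It was 1 for the interaction without Raf-inactive normoxia replicate 1 or 4, Raf-active normoxia replicate 4, Raf-inactive hypoxia replicate 2 or 4 or Raf-active hypoxia replicate 1 or 2. Loci changed ran from 9020 to 9590, 8529 to 9143, 1538 to 2063, 3597 to 4278 and 2519 to 2852 in that order.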

Other observations

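The tests here were all chosen only after the results were seen, apart from the list tests, which were planned.

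Gene groups outside the accounts above also held loci that moved with hypoxia. Of all 15175 loci, hypoxia moved 970 up and 1121 down in Raf-inactive cells, and 2061 up and 2160 down in Raf-active cells. In Raf-inactive cells 7 of 50 secretory genes rose and 3 fell, or 9 and 3 adjusted over the list alone (adjusted p 0.212). In Raf-active cells 10 of 65 histone genes rose and 3 fell, or 8 and 2 adjusted over the list alone (adjusted p 0.351). There 7 of 31 interferon response genes rose and 1 fell, or 9 and 1 adjusted over the list alone, and 6 of 29 HOX genes rose and 1 fell. Of 21 histone lysine demethylases 1 rose and 7 fell, or 2 and 7 adjusted over the list alone (adjusted p 0.496), and of 34 methyltransferases 4 rose and 10 fell (adjusted p 0.351). None of these lists passed the camera test.

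The hypoxia responses of Raf-inactive and Raf-active cells shared few loci. Of the loci called in each, 231 rose in both, against 132 for independent lists, and 228 fell in both, against 160, while 94 and 102 went opposite ways. Across loci, which are not independent replicates, Spearman's rho between the changes was 0.14, against 0.78 between the Raf changes in normoxia and hypoxia. EGLN3 and ANKRD37 were among those that rose in both.

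Of the regions gained with Raf in normoxia, 63.1% had a peak in 4 of 4 Raf-active hypoxia libraries and 16.2% in none.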
